A study of Mus musculus with 4 samples.

How the data were processed

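RNA was extracted from brains of C57BL/6 mouse embryos at stage E13.5 with Trizol and 2 KO and 2 WT libraries were sequenced, per the labels' protocols. Each sample was placed in its group by the genotype in its title and characteristics, and its number (2, 4, 6 or 8) is the one in its title. The 2 libraries of each genotype differ in sex by their transcripts and so came from different embryos. The labels do not say whether these were of separate litters, so p-values measure the spread between these samples, which may in part be technical. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 and the genome build mm9, without saying how each was used. The positions in the tables, however, were identical to GENCODE M21 on GRCm38 (mm10) for 91.4% and 91.5% of genes, so positions are given here on GRCm38. Whether the library kit kept strand, and whether counting used it, is not given in the sources used here.

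The authors deposited 2 tables, each with a read count per gene for 1 KO and 1 WT library, and the counts are whole numbers that were not normalized, per the file headers and the values. The deposited normalized value is a CPM: the authors divided each count by a library total that includes between 2721 and 3820 reads of genes not listed (at most 0.0211%), and a count of 0 was given the CPM of 0.5 read, as found from the values. The authors' tables also hold a linear fold change (ratio) of KO over WT, its log2, a p-value and an adjusted p-value per gene, per the file headers; the test behind the p-values is not given in the sources used here. Their mark of significance was found from the values to mean an adjusted p under 0.05 and an absolute log2 fold change of at least 1, and it is carried by 376 genes for KO2 over WT6 and 1032 for KO4 over WT8. A gene with 1 count of 0 has at least 5 reads in the other library, so genes with few reads can be missing from a table, and 1103 and 1274 genes are in 1 table alone. Total counts were between 16470090 and 18136745 per library.

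Counts of the 19150 genes in both tables were joined by gene identifier and analysed in R 4.3.3. The main test was edgeR 4.0.16 with its quasi-likelihood F-test on all 4 libraries, genotype as the only term, TMM normalization, genes kept by filterByExpr (15708) and Benjamini-Hochberg adjustment over them, with a threshold of 0.05. Log2 fold changes are KO over WT, their SE is the fold divided by the root of the F statistic, and CPM values are scaled by the TMM factors, which lay between 0.971 and 1.01. Ratios within a pair are of log2 CPM with a prior count of 2. Before the data were examined, 38 gene lists were fixed for the cell types, regions, pathways and tissues that a dissected brain of this age could hold, and 34 had at least 5 measured members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. In single pairs no test was run, and the median of a list was placed among 10000 random lists of the same size matched on mean expression. Exact intervals and Poisson intervals are at 95% and cover counting error only.

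The genes to be named were fixed by a rule at the same time: the macroH2A genes H2afy and H2afy2; Nkx2-2; the 12 higher and 12 lower genes with the largest fold among those that passed at a mean of at least 1 CPM with both KO libraries on the same side of both WT libraries; where fewer than 10 passed in a direction, those with the smallest p up to 10; the 2 to 4 members with the smallest p of each list discussed, and the 3 most abundant members of lists of other cell types; and Xist with 4 Y-linked genes. Genes outside this rule are said to have been named after their values were seen.

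The fit was tested on simulated counts drawn from the means, library sizes and dispersions of these 15708 genes, with 200 genes changed by known folds in each of 10 rounds. The edgeR fit recovered 29.4% of genes changed 1.5-fold, 68.0% of those changed 2-fold and 92.6% of those changed 4-fold, with 190 calls among unchanged genes over the 10 rounds beside 1441 correct ones, so that 11.6% of its calls were false and the threshold of 0.05 was not held. The shares recovered were not measured with fewer genes changed at once. Camera at the preset correlation called 33 of 34 lists whose members were raised by 0.5 on the log2 scale. Genes were drawn independently there and calls of unchanged lists were not counted. Neither its power for genes that move together nor its false calls were therefore measured. Camera with an estimated correlation and fry were not tried on simulated lists. Alternatives fixed at the start were other normalizations and filters, DESeq2 1.42.0, limma-voom, limma on the deposited CPM, the deposited pair or the sex of the embryo as a term, and the fit without each library in turn. An alternative with a pseudocount of 0.1 was meant for tables without counts and did not apply. Gene length and GC content came from the longest GENCODE M21 transcript of each gene and were known for 15687 of the genes tested. Genes in 1 table alone were left out of the main test.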

Results

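Brains of E13.5 mouse embryos were profiled by RNA sequencing to ask which transcripts differ when macroH2A has been deleted. MacroH2A is a variant of histone H2A that carries a large additional domain, and mice have a pair of genes for it, H2afy (macroH2A1) and H2afy2 (macroH2A2). The labels give 2 knockout brains (KO2 and KO4) and 2 wild-type brains (WT6 and WT8), all on the C57BL/6 background, and do not say which of the macroH2A genes was targeted. The authors deposited their values as 2 tables, each with 1 KO library beside 1 WT library, KO2 with WT6 and KO4 with WT8. The total read count in the tables was 18136745 for KO2, 18079127 for KO4, 17151485 for WT6 and 16470090 for WT8, so that depth differed little between libraries. The tables list 20253 and 20424 genes, of which 19150 are in both, and 15708 of these held enough reads to be tested.

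H2afy was the macroH2A gene with reduced transcript in the knockout brains, and H2afy2 was at a similar level in both genotypes. H2afy (ENSMUSG00000015937, chromosome 13, 56073619 to 56136361 on GRCm38) had 1368 reads in KO2, 1267 in KO4, 5538 in WT6 and 5593 in WT8. This corresponds to 71.9 ± 3.88 CPM (the read count scaled to the size of the library) in KO and 336 ± 20.02 CPM in WT (mean ± SD, n = 2 libraries each), a log2 fold change of -2.22 (SE 0.10, edgeR quasi-likelihood adjusted p = 0.00167), and KO transcript was 0.214 times that of WT. Reads over H2afy were therefore still present in both KO libraries, and the tables give no value per exon that would place them inside or outside the deleted part. H2afy2 (ENSMUSG00000020086, chromosome 10, 61738665 to 61784147) had 198 ± 11.4 CPM in KO and 187 ± 6.91 CPM in WT, a log2 fold change of 0.08 with a 95% interval from -0.13 to 0.30 (edgeR adjusted p = 0.799). Leaving out WT6 kept the H2afy fold at -2.29 on the log2 scale but ended its call (edgeR adjusted p = 0.314). Its adjusted p ranged from 2.81e-72 with DESeq2 to that value over all alternatives, and it passed without each of the other libraries.

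**Figure D1:**
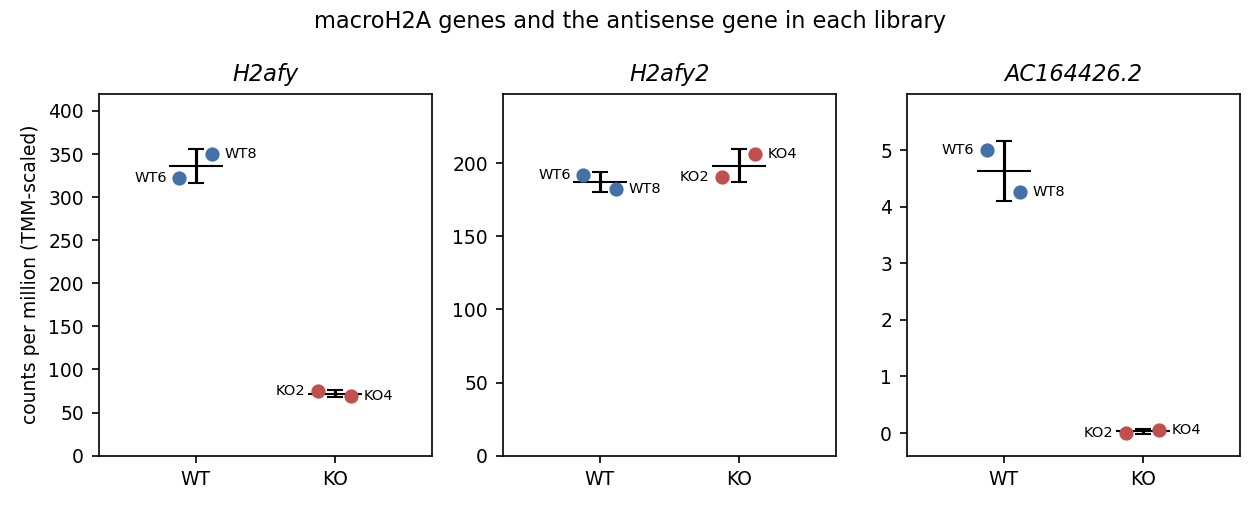
Transcript level in CPM scaled by TMM factors (vertical axes), for H2afy, H2afy2 and the antisense gene AC164426.2, in the 2 WT and 2 KO libraries. Points are single libraries, the horizontal bar is the group mean and the whisker its SD; H2afy averaged 336 CPM in WT and 71.9 CPM in KO, while H2afy2 averaged 187 and 198 CPM.

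A noncoding gene on the opposite strand, AC164426.2 (ENSMUSG00000114493), was nearly without reads in the knockout brains. It had 0 reads in KO2 and 1 in KO4 against 86 in WT6 and 68 in WT8, so that KO held 0.588% of the WT reads per unit of depth, with an exact counting interval of 0.0148% to 3.32% that covers counting error only. The deposited tables place it on chromosome 13 from 56002265 to 56084849 on the plus strand, and its last exon in the GENCODE M21 annotation (56082860 to 56084849) covers 2 exons of H2afy, which lies on the minus strand, over 175 and 326 bases. The counting is not stated to have used strand, so reads of AC164426.2 and of H2afy cannot be told apart over that exon, and the counts of AC164426.2 are uncertain. Its edgeR adjusted p was 0.0626, which misses the threshold, and 0.0281 with the deposited pair as a block, and over all alternatives it ranged from 2.35e-07 without WT8 to 0.314 without WT6. Without KO4 it was 0.00856. The other 47 tested genes whose start lay within 2 Mb of that of H2afy had a median log2 fold change of -0.07, and none of them passed in edgeR, with 2 at an unadjusted p under 0.05.

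**Figure D2:**
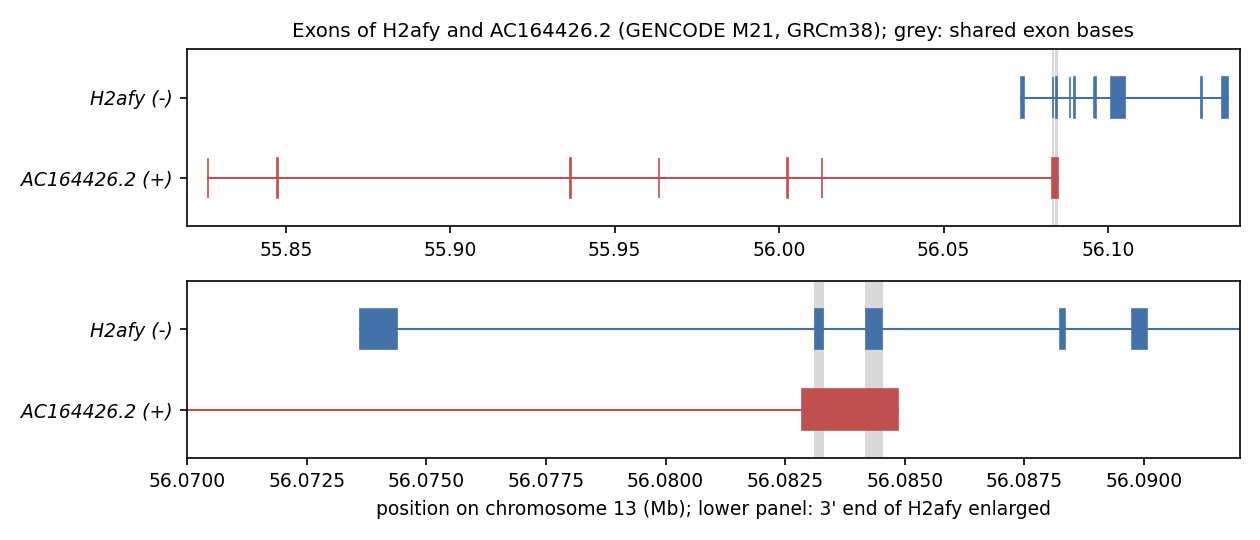
Exons of H2afy and AC164426.2 in the GENCODE M21 annotation along chromosome 13 in megabases (GRCm38), with the region at the 3' end of H2afy enlarged in the lower panel. Boxes are exons, lines span each gene, and grey bands mark the 175 and 326 exon bases that both genes share.

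Across all genes, H2afy was the single gene that edgeR called different between KO and WT brains. Of the 15708 genes tested with edgeR, 0 rose and 1 fell in KO at an adjusted p under 0.05, and 738 had an unadjusted p under 0.05, where 785 would be given by chance. Limma-voom gave 0 higher and 1 lower, and DESeq2 gave 2 higher (Fam96b and Hnrnpab) and 2 lower (H2afy and AC164426.2). The median 95% interval of a gene's log2 fold change reached 0.34 to either side, and 0.26 for genes at a mean of at least 10 CPM. In simulated counts with the spread of these libraries, the same fit recovered 68.0% of genes changed 2-fold and 29.4% of genes changed 1.5-fold. Of the calls made there, 11.6% were false. Many genes were changed at once there, some of them 8-fold, which loosens the adjusted threshold, and genes were drawn independently. Recovery was not measured with few genes changed or with genes that move together. These shares therefore do not say how many changes were missed here. The count rested on the WT libraries: without WT8 the edgeR fit called more genes in both directions, and without WT6 it called no gene. Either fit holds 1 WT library and takes its spread from the KO libraries alone.

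None of the genes nearest to the threshold on the higher side passed the edgeR test. Fam96b, a component of the cytosolic iron-sulfur protein assembly machinery, had 66.6 ± 6.89 CPM in KO and 40.0 ± 1.18 CPM in WT (n = 2 each), a log2 fold change of 0.73 (SE 0.10, edgeR adjusted p = 0.743). The RNA-binding protein gene Hnrnpab had 392 ± 19.9 CPM in KO and 258 ± 18.1 CPM in WT, a log2 fold change of 0.60. Zbtb33, which encodes the methyl-CpG-binding protein Kaiso, had a log2 fold change of 0.59, the mitochondrial glycerol-3-phosphate dehydrogenase gene Gpd2 one of 0.51, the ETS factor gene Etv1 one of 0.46 and the atypical chemokine receptor gene Ackr3 one of 0.39. Eri2 stood at 0.88, and Chsy3, a chondroitin sulfate synthase gene, at 1.94 on counts of 18 and 25 in KO and 5 and 5 in WT. The remaining pair, Gm10052 at 0.50 and Gm5518 at 0.38, are annotated as processed pseudogenes, whose reads can be shared with their parent genes. For all 10 of these genes both KO libraries lay above both WT libraries, and all had an adjusted p of 0.743 in edgeR. Genotypes whose libraries did not overlap were found for 6196 genes, or 39.4%, where chance gives 33.3%. Fam96b and Hnrnpab passed with DESeq2 (adjusted p of 0.00601 and 0.00193). Both also passed in edgeR without WT8, a fit with 1 WT library whose spread comes from the KO libraries alone.

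On the lower side, after H2afy and AC164426.2, none of the genes nearest to the threshold passed. Emx1, a homeobox gene of the dorsal telencephalon, had 141 ± 5.79 CPM in KO and 196 ± 2.16 CPM in WT (n = 2 each), a log2 fold change of -0.47 (SE 0.08, edgeR adjusted p = 0.743). Rnd2, a gene active in migrating cortical neurons, stood at -0.36, and Ppp1r1b, which encodes DARPP-32, at -0.50. Inppl1 stood at -0.38, Suox, the sulfite oxidase gene, at -0.58, the phosphatase gene Ctdsp1 at -0.34 and the ribosomal protein gene Rpl23a, which has processed pseudogenes that can share its reads, at -0.66. The noncoding gene Gm42031 had 0 and 1 reads in KO and 13 and 12 in WT. Nkx2-2, a homeobox gene of the ventral neural tube named in advance, had 7 reads in KO2, 5 in KO4, 3 in WT6 and 46 in WT8, too few for the filter. Tested without a filter it had a log2 fold change of -2.18 (SE 1.1, edgeR adjusted p = 0.775), and the WT value rested on WT8. Without WT8, edgeR called Emx1, Rnd2 and Ppp1r1b lower in KO. That fit holds WT6 as its only WT library and takes its spread from the KO libraries alone, so these calls do not speak of the genotypes.

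None of the 34 gene lists with at least 5 measured members was called by camera, the test of a list against all other genes. GABAergic and ventral forebrain genes came nearest on the higher side, with 18 of 21 measured members above 0, a median log2 fold change of 0.20 and a camera adjusted p of 0.0629. WT6 was the lowest of the 4 libraries for 20 of the 21. None of the 21 passed the edgeR test over all genes or adjusted over the list alone. Its members with the smallest p were Ebf1 at 0.53, Sp9 at 0.45, Lhx6, a factor of cortical interneurons, at 0.27 and Gsx2 at 0.41. The dorsal telencephalon list, with 14 measured members and a median of -0.15, had a camera adjusted p of 0.135. Within it Emx1 was lower in KO adjusted over the list alone and not over all genes, and Emx2 at -0.20 and Lhx2 at -0.24 did not pass either way. At an unadjusted p under 0.05 camera gave 7 lists. With the deposited pair as a block it called the GABAergic list (adjusted p = 0.01001), as it did after removing the GC content and length trend (0.000746), where 27 of the 34 lists kept their direction. With an estimated correlation all lists had an adjusted p of at least 0.935. As 0 lists then had an unadjusted p under 0.05, that setting may be too weak here to decide on a list. The GABAergic list was called higher without WT8 and without KO4, and without WT6 it lay on the lower side and was not called. The dorsal telencephalon list was called lower without KO2 and without WT8. Each fit without a library holds 1 library of a genotype and takes its spread from the other genotype alone. Fry, which tests a list against no change and not against other genes, gave the GABAergic list an adjusted p of 0.995. With an estimated correlation no list was called whichever library was left out (smallest adjusted p 0.919).

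Lists of cell division and of chromatin were not called either. G2/M genes, 18 of 25 above 0, had a median log2 fold change of 0.13 and a camera adjusted p of 0.0673, led by the spindle protein gene Prc1 at 0.51, the cyclin gene Ccna2 at 0.29 and the centromere protein gene Cenpf at 0.23. S phase genes had a median of 0.02 and p53 targets one of -0.10, with adjusted p of 0.736 and 0.767. Among 11 macroH2A and other histone variants, 1 fell (H2afy), 10 did not pass, and the camera adjusted p was 0.0725, which rested on H2afy, as it was 0.380 without that gene. H2afj stood at -0.38 and H1fx at -0.27. The replication-dependent histones had a median of -0.23 over 17 measured members (adjusted p = 0.323), Polycomb and chromatin regulators one of 0.05 over 28 (adjusted p = 0.584) and imprinted genes one of -0.03 over 29 (adjusted p = 0.751). The replication-dependent histones, listed in advance as a sign of RNA or library quality, differed more between the deposited pairs than between the genotypes. Their median deviation from the mean of all libraries was -0.58 in KO2 and -0.47 in WT6, against 0.28 in KO4 and 0.79 in WT8. KO2 was the lowest library for 9 of the 17 and WT6 for 7. A fit that leaves out a library holds the pairs unevenly, so its calls of this list do not speak of the genotypes. Apart from H2afy, no member of the lists in this paragraph passed, adjusted over the list alone or over all genes. Rbbp4 at 0.30 and Ring1 at -0.33 were the Polycomb list members with the smallest p, and Mest at 0.41 and Cdkn1c at -0.52 those of the imprinted list, whose median and camera direction differed in sign. G2/M genes were called higher without KO2 (adjusted p = 0.0473) and without WT8 (0.00269), and imprinted genes without WT8 (0.00625). Replication-dependent histones were called lower without WT6 (0.0143) and without KO4 (2.11e-05), and histone variants without WT6 (0.0143), though not with H2afy also left out (0.0521). None of these calls was made with an estimated correlation, a setting that was not tried on simulated lists and may be too weak here to decide.

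Lists of neural cell identity and signalling were not separated from other genes. The 7 lists of radial glia, intermediate progenitors, postmitotic neurons, glial lineages, synapse, axon guidance and autism risk genes had medians between -0.08 and 0.08 and camera adjusted p between 0.169 and 0.934. Autism risk genes, which the title of the series touches on, had 30 of 39 measured members above 0, a median of 0.08 and an adjusted p of 0.169, with Cul3 at 0.21 and Foxp2 at 0.41 nearest to the threshold. The median log2 ratio of the list was -0.03 in KO2 over WT6 and 0.15 in KO4 over WT8. These lay at percentiles of 31.4 and 99.9 of random lists of like expression. WT8 was the lowest library for 27 of the 39, so the higher values came mostly from the second pair. Ptprz1 at 0.21 and Ednrb at 0.23 led the radial glia, Rgs16 at -0.22 and Gadd45g at -0.18 the intermediate progenitors, and Rbfox3, which encodes NeuN, at -0.23 and Nefm at 0.23 the postmitotic neurons. The Notch, Hedgehog and Wnt lists had adjusted p between 0.139 and 0.900, with Jag1 at 0.42 and Wnt7b at -0.28 as the members with the smallest p in the Notch and Wnt lists. Immediate early, hypoxia and glycolysis, interferon and mitochondrially encoded genes had adjusted p between 0.323 and 0.767. In none of these lists did a member pass over all genes or adjusted over the list alone. The floor plate list (7 measured members, median -0.11), the diencephalon and midbrain list (12, -0.06) and the hindbrain list (5, 0.10) had adjusted p of 0.773, 0.767 and 0.736, and no Hox gene had a value in either table used here. Median and camera direction differed in sign for postmitotic neurons, Hedgehog and interferon genes. Single libraries changed some calls: autism risk genes were higher without WT6 (0.0153), Wnt genes lower without KO2 (0.0152), mitochondrially encoded genes higher without WT8 (0.0411), and floor plate genes lower without WT6 (0.0153) and higher without WT8 (0.00625). None of these was called with an estimated correlation, which may be too weak here to decide.

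Transcripts of cells other than neural cells were present in all libraries, and none of their lists was called. Microglia and macrophage genes had 5 of 16 measured members above 0, a median of -0.24 and a camera adjusted p of 0.0629. Their median was -0.07 in KO2 over WT6 and -0.49 in KO4 over WT8, at percentiles of 14.8 and 0.1 of random lists of like expression, so the lower values came mostly from the second pair. The adjusted p was 0.935 with an estimated correlation, 0.01001 with the deposited pair as a block, 0.204 after removing the GC content and length trend and 0.0108 without KO2. Its 3 most abundant members differed little, Cd68 at -0.10, Laptm5 at 0.05 and Csf1r at -0.11. Lower members included Mrc1 at -1.48, on 5 to 21 reads per library, and C1qa at -0.52, on 90 to 143. As Csf1r had 134 to 167 reads, the lower members were not the scarce ones alone. Erythroid genes had a median of -0.25 (adjusted p = 0.767), and Hbb-y, the embryonic beta-like globin gene, had 177 CPM in KO2, 227 in KO4, 134 in WT6 and 426 in WT8. Endothelial genes had a median of -0.06 (adjusted p = 0.323) with Slc2a1 at -0.23, Rgs5 at -0.04 and Mfsd2a at 0.03. Meningeal genes stood at -0.16 and choroid plexus, muscle and cartilage genes at 0.07, -0.15 and 0.03, and ganglion genes at -0.03, with adjusted p between 0.584 and 0.900, and for choroid plexus, cartilage and ganglion genes the median and the camera direction differed in sign. No member of these lists passed, over all genes or adjusted over the list alone. The 3 measured genes of surface epithelium and the 3 of eye and pituitary are too few for a test, and Pomc among the latter had 9.02 CPM in WT8 and 2.89 to 3.55 CPM in the other libraries.

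The 2 pairs of libraries, as the authors compared them, shared few large changes. The authors' deposited tables give an adjusted p under 0.05 to 1738 genes higher and 1756 lower in KO2 against WT6, and to 4854 higher and 3111 lower in KO4 against WT8. Each of these comparisons sets 1 library against 1, so its p-values speak of those libraries and not of the genotypes. Among the 19150 genes in both tables, 595 were called higher in both pairs, where independent lists of that size would share 437, and 315 lower in both, where they would share 282. Called in opposite directions were 1250 genes, where independent lists would share 720. Genes with many reads are called more easily in each pair. An excess over independent lists in the same and in opposite directions can therefore arise without a shared effect. With a log2 change of at least 1 in each pair, 12 genes were higher in both, where independent lists would share 7.94, 4 were lower in both (2.17 by chance) and 70 went in opposite directions (8.58 by chance). The 4 lower were H2afy, AC164426.2, Gm42031 and Gm7551, the last of them named after its values were seen. In the authors' deposited tables H2afy had log2 fold changes of -2.10 and -2.28.

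Some genes of the ventral forebrain, named here after their values were seen, went apart between the pairs. In the authors' deposited tables the homeobox gene Nkx2-1, of the ventral forebrain and hypothalamus, had a log2 ratio of 2.54 in KO2 over WT6 and of -0.66 in KO4 over WT8, on 1787, 290, 1307 and 1880 reads in KO2, WT6, KO4 and WT8. Otp, a hypothalamic homeobox gene, had ratios of 1.52 and -1.46. Isl1 had ratios of 1.37 and -0.24. The whole GABAergic and ventral forebrain list had a median log2 ratio of 0.78 in the first pair and -0.18 in the second, against 10000 random lists of like expression at percentiles of 100 and 1.24. In the first pair the dorsal telencephalon list had a median of -0.22, and in the second -0.09.

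**Figure D3:**
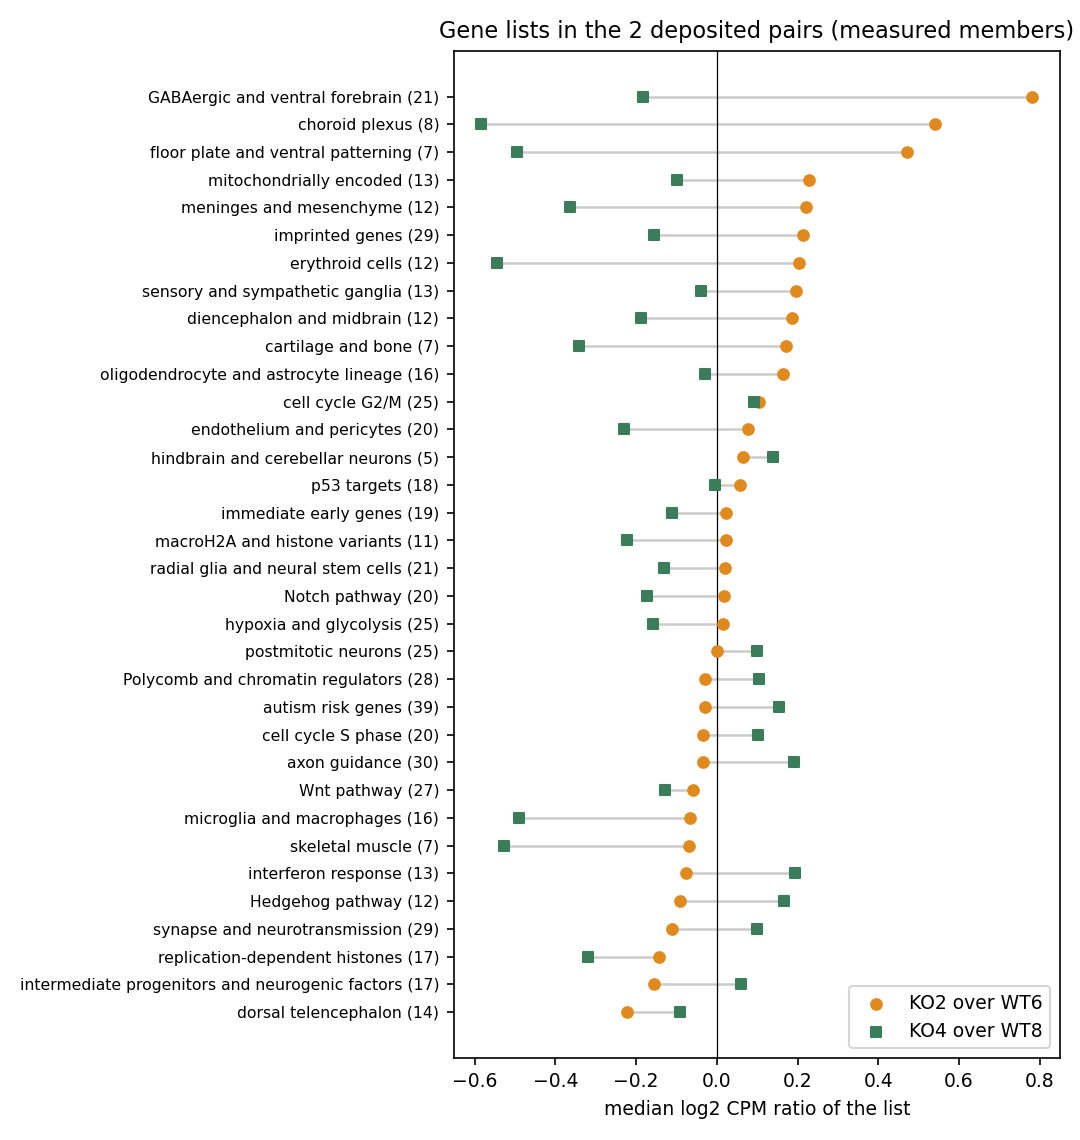
Median log2 CPM ratio of KO over WT for each of the 34 gene lists with at least 5 measured members, in the pair KO2 over WT6 (circles) and the pair KO4 over WT8 (squares). The number of measured members stands in brackets; the GABAergic and ventral forebrain list lies at 0.78 in the first pair and at -0.18 in the second.

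Over all 15708 genes, the KO to WT ratios of the 2 pairs were not positively related. Pearson's r across genes was -0.17 and Spearman's rho -0.07, and 49.9% of genes had the same sign in both pairs. With the libraries paired the other way, KO2 with WT8 and KO4 with WT6, r was -0.05 and rho 0.18, and 61.6% of genes had the same sign. Each ratio of this pairing sets a male against a female profile, in opposite senses, so Xist and Y-linked genes lower its r. The r values of the pairings are not directly comparable for this reason. The rho of 0.18 became 0.37 among genes at a mean of at least 10 CPM and 0.0552 after removing the GC content and length trend. Genes are not independent replicates, so these values describe the 4 libraries and carry no p. The libraries were alike as whole profiles, with Spearman correlations of log2 CPM from 0.989 (KO4 with WT8) to 0.994 (KO2 with KO4). The first principal component, with 47.7% of the variance, placed WT8 at -35.0 and the others between 0.700 and 19.7, so that the 2 WT libraries lay at its ends.

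**Figure D4:**
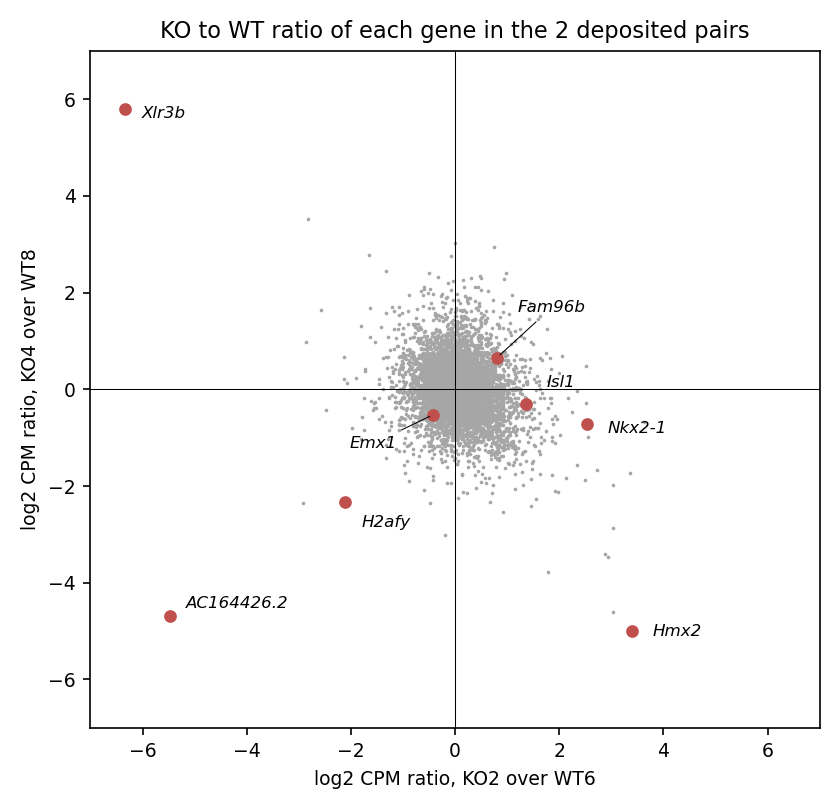
Log2 CPM ratio of KO4 over WT8 against that of KO2 over WT6 for 15708 genes, each a grey point, with named genes in red. H2afy and AC164426.2 lie low in both pairs, while Nkx2-1, Hmx2 and Xlr3b, marked after their values were seen, lie on opposite sides of 0.

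Sex differed between the pairs and not between the genotypes. Xist, which is transcribed from the inactive X chromosome of females, had 8105 reads in KO4 and 6094 in WT8, against 6 in KO2 and 19 in WT6. The Y-linked gene Eif2s3y had 1150 reads in KO2 and 697 in WT6 and 1 in each of KO4 and WT8, and Kdm5d had 729, 624, 1 and 1. Ddx3y and Uty, also Y-linked, were listed in the table of KO2 and WT6 alone. Each genotype therefore held 1 male and 1 female profile, and a term for sex in the edgeR fit is the same as the pair block, with 0 genes higher and 2 lower.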

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

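All tests in this part were chosen after the patterns they bear on had been seen. Some values differed between the pair of male profiles, KO2 and WT6, and the pair of female profiles, KO4 and WT8, and with 1 library per sex and genotype no fit that also holds genotype and sex can test them. Fitted as the only term in edgeR, the split of KO2 and WT8 against KO4 and WT6 passed for Xlr3b (adjusted p = 1.42e-07) and Otp (0.0156), both picked for this pattern. It did not pass for Nkx2-1 and Isl1, which had also been named as going apart between the pairs. The median log2 ratio of KO over WT went in opposite directions in the pairs, outside the central 95% of random lists of like expression in each, for GABAergic and ventral forebrain genes (0.78 and -0.18, a difference of 0.964), floor plate and ventral patterning genes (0.47 and -0.49, 0.966), choroid plexus genes (0.54 and -0.58, 1.12) and erythroid genes (0.20 and -0.54, 0.749). For the GABAergic list this came mainly from WT6, whose median deviation from the mean of the 4 libraries was -0.58, against 0.17 in KO2, 0.10 in KO4 and 0.27 in WT8. Xist had log2 ratios of -1.74 and 0.28 in the authors' deposited tables, a difference of -2.02, on 6 and 19 reads in the male pair.

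The opposite directions of the ventral forebrain genes were taken up first, as their list held the most measured members of these lists, 21. A candidate explanation is that the dissected brains held different amounts of ventral and hypothalamic tissue. The list for its test was drawn up after Nkx2-1, Six6, Hmx2 and Hmx3 had been seen to go apart, held 22 genes, and was shortened to 17 by dropping 5 less certain markers before its members were looked at one by one. Of these, Rax and Lhx9 also stand in lists that had been analysed by then, and all of these genes can be transcribed in brain. Of the 17, 11 had enough reads, and 8 lay above WT6 in KO2 and below WT8 in KO4, which is 72.7% against 24.8% of all genes (exact interval 39.0% to 94.0%, one-sided exact binomial p = 0.00111, with genes taken as independent), and the 22 gave 11 of 14 (one-sided exact binomial p = 3.63e-05). Without Rax and Lhx9 it was 7 of 10 (exact interval 34.8% to 93.3%, one-sided exact binomial p = 0.00331), and 6 of the 11 had fewer than 30 reads in each library, and some of the 8 hardly moved, such as Lhx9 with log2 ratios of 0.07 and -0.15, while Tbx3 had 1.14 and -0.88. WT6 was the lowest library for 7 of the 11. Pseudogenes went the same way in 52.3% of 725 and other protein-coding genes in 23.4%, so a technical difference along the same split of the libraries is not excluded. The same values would arise if the deletion acted differently in male and female embryos, which cannot be told apart here, because a fit with genotype, sex and their interaction leaves 0 residual degrees of freedom.

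Xlr3b, an X-linked gene, had 0 reads in KO2, 114 in KO4, 157 in WT6 and 0 in WT8, so that the authors' deposited log2 ratios were -8.38 and 7.70, a difference of -16.1. Reads moved from Xlr3b to counted copies would leave their sum level. The summed CPM of Xlr3a, Xlr3b and Xlr4a differed 63.4-fold between the highest and the lowest library. It ran from 0.182 (Poisson interval 0.0376 to 0.532) in WT8 to 11.5 (9.99 to 13.3) in WT6. This argues against such a move for copies listed in both tables alone. Xlr3b itself gave 114 of the 164 summed reads in KO4 and 157 of the 198 in WT6. Reads left uncounted because they matched more than 1 copy would not keep the sum level, and this was not tested. An X chromosome segment from another parent or strain may also be considered: 8 of 75 tested genes within 5 Mb, or 10.7% (exact interval 4.72% to 19.9%), were higher in KO4 and WT6, against 19.8% of all genes, and this does not decide it, since a segment need not change its other genes. The genotype is no account of it by itself, as 1 library of each genotype had the reads.

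Reads of genes listed in 1 table alone stayed outside the main test. In the table of the male pair these were led by the Y-linked genes Ddx3y with 740 reads, Gm29650 with 435 and Uty with 319 over KO2 and WT6, and the most in the table of the female pair was 51 reads.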

How the results depend on the processing

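The settings with a GC content and length trend, with genes absent from a table counted as 0, without 7 loci of rRNA-like and small RNA, with H2afy left out of its list, with Gene Ontology terms, and with an estimated correlation while single libraries were left out were added after seeing the data. H2afy was called lower under all settings except without WT6, where its adjusted p was 0.314 in edgeR; its log2 fold change ran from -2.29 (without WT6) to -2.16 (without WT8) with single libraries left out. Genes lower in KO numbered 2 in place of 1 with library size alone, DESeq2, an adjusted p under 0.1, the deposited pair as a block, sex as a term, limma on the deposited CPM, and the GC content and length offset with or without the block, in each case H2afy and AC164426.2. Genes higher in KO numbered 2 with DESeq2. Leaving out each replicate in turn gave from 0 to 67 higher and from 0 to 37 lower, both highest without WT8, with 1 WT library then assumed to vary like the KO libraries. No pairing by replicate number was possible because the labels give the groups no shared numbers, and the block above follows the deposited tables instead. Lists called higher numbered 1 with the pair as a block and 1 after removing the GC content and length trend, in both cases the GABAergic list, and lists called lower 1 with the block. Leaving out single libraries gave 1 to 5 lists higher and 1 to 3 lower. With an estimated correlation 0 lists were called, with all libraries (smallest adjusted p 0.935) or without any 1 of them. That setting also gave 0 lists at an unadjusted p under 0.05 with all libraries, so it may be too weak to decide. The floor plate list turned from a median below 0 to a call on the higher side without WT8 (adjusted p = 0.00625), and its adjusted p was at most 0.966 (without KO4) with single libraries left out. Of 2586 Gene Ontology terms, 5 were lower in KO, 4 with the pair as a block and 0 with an estimated correlation (smallest adjusted p 0.999). Genes called in both deposited pairs numbered 12 higher and 4 lower with a log2 change of at least 1, and 298 and 152 with an adjusted p under 0.01. For the pairing of KO2 with WT8, whose ratios cross the sexes, r was -0.20 and rho 0.37 among genes at a mean of at least 10 CPM. Its rho was 0.0552 after removing the trend. Whether correlations between pairs and between libraries had moved was judged by tolerances of 0.1 and 0.005, set after their main values were known. Over the 500 most variable genes, correlations between libraries ran from 0.365 to 0.595. The causes of these changes were not tested. Of 412 values of 22 other named genes, 395 kept their side of the threshold and 17 passed it, and of 340 values of single lists 321 kept their side of the threshold. Depth limits genes with few reads, such as Nkx2-2, which the filter removed.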

Other observations

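All tests in this part were chosen after the data had been seen. Protein-coding genes of the ribosome lay lower in KO4 than in WT8, and camera calls for them were lost with an estimated correlation. Among 2586 Gene Ontology terms of 13578 protein-coding genes, camera called structural constituent of ribosome (218 genes, 181 below 0, median log2 fold change -0.15, adjusted p = 0.00021), the cytosolic large subunit (68 genes, -0.18), the cytosolic small subunit (42 genes, -0.21), translation (210 genes) and ribosomal small subunit assembly (16 genes) lower in KO. With an estimated correlation no term was called and the smallest adjusted p was 0.999. That setting was not tried on simulated data and may be too weak here to decide. The median of the first of these terms was 0.03 in KO2 over WT6 and -0.34 in KO4 over WT8, so the first pair did not show the drop. Ribosomal small subunit assembly was not called with the deposited pair as a block (adjusted p = 0.07195) or after removing the GC content and length trend (0.3225). The other 4 terms stayed called with the block and after the trend was removed, and the mitochondrial large ribosomal subunit was then called as well (0.013). No member of these terms passed on its own in edgeR. The terms were redefined after a first run, in which 1505 terms of 15708 genes, of 15 to 500 genes each and without molecular functions, gave 4 calls, all lower.

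The 4 libraries can be split into groups of 2 and 2 in 3 ways, and edgeR called 1 gene for the split by genotype, 11 for the split by deposited pair, which is also that by sex, and 125 for the remaining split, KO2 and WT8 against KO4 and WT6. With 3 splits no share under 0.05 can be had. The 125 calls point to a structure of the libraries, and because this split is also the contrast of the genotype difference between the sexes, its cause is left open. Gene length followed the same split: the deviation of a library from the mean had a rho with length of 0.31 in KO4 and 0.14 in WT6. It was -0.03 in KO2 and -0.34 in WT8. GC content did not follow it, with -0.35 in KO4, 0.09 in WT6, -0.26 in KO2 and 0.35 in WT8. This split was not fitted with the GC content and length trend removed, so how many of the 125 calls rest on that trend is not known. The 11 genes of the split by pair held Xist, Kdm5d, Eif2s3y and Gm15446, a gene on chromosome 5 with 6.77 and 6.45 CPM in KO2 and WT6 and 1 read in each of the others. The other 7 were Gm26917, Gm23935, CT010467.1, Lars2, Rn7sk, Gm24270 and Rpph1, which are annotated as rRNA, microRNA or other noncoding genes apart from the protein-coding Lars2; together they took 0.651% of reads in KO4 and 0.431% in WT8, against 0.106% in KO2 and 0.130% in WT6. Of the 125, 43 were pseudogenes (5.93% of those tested, against 0.516% of protein-coding genes outside the mitochondrial genome), 41 of them higher in KO2 and WT8. A further 4, also higher there, were mitochondrially encoded, such as mt-Co2 with 2799 reads in KO2, 3424 in WT8, 1704 in KO4 and 1363 in WT6. The total of all mitochondrially encoded genes did not follow this split. It was 2.543% of reads in KO2, 2.235% in WT8, 2.324% in KO4 and 2.226% in WT6. Differences in RNA quality, or in how reads were shared between copies, were not tested. Other genes among the 125, picked after their values were seen and not tested as a group, were Hmx2 with 20 reads in KO2, 85 in WT8, 1 in KO4 and 0 in WT6, and Fgf15 with 506, 452, 143 and 107.

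The KO4 and WT8 libraries differed in more genes than KO2 and WT6, with a median absolute deviation of the log2 ratio of 0.228 against 0.138. More reads in the KO4 and WT8 libraries would be a possible explanation, but their summed count was 0.979 times that of the other pair. A GC content and length trend could also widen a ratio, and WT8 deviated from the mean of the libraries with a rho of -0.34 with length and 0.35 with GC content across genes, while KO4 deviated with 0.31 and -0.35. After the trend was removed the deviations were 0.164 and 0.121, a ratio of 1.36 (bootstrap interval 1.32 to 1.39) against 1.66 before. The interval comes from drawing genes again and does not cover variation between libraries. In these 4 libraries the fitted trend thus took up part of the difference and not all of it. Differences between the embryos, their dissections or their RNA quality were not tested and remain open.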
